A study of Mus musculus with 28 samples.

How the data were processed

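The series follows gene expression in rod photoreceptors of the mouse retina from postnatal day 2 to postnatal day 28. Retinas came from C57Bl/6 mice that carry the Nrlp-GFP transgene, in which the promoter of the rod gene Nrl drives green fluorescent protein. Per the labels' protocols, retinas were dissociated with papain, GFP-positive cells were collected by fluorescence-activated sorting, and sorted samples were kept only when a re-sort gave a purity of 97% or more. Per the labels, 5 ng of total RNA with an integrity number above 7 was amplified with a whole-transcript kit and hybridised to Affymetrix Mouse Exon 1.0 ST arrays, 1 array per sample.

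The values used were those of the deposited table, on a log2 scale. Per the submitters' processing notes, the authors made them with RMA (background correction, quantile normalization and a summary over probes) in Affymetrix Expression Console 1.3.1.187, at gene level over the core probe sets as mapped to the mm8 mouse build. The log2 scale was read from the values, which ran from 1.87 to 13.79. Array medians lay between 6.72 and 7.00, at 6.87 or higher in every array of P2, P4 and P6 and at 6.85 or lower in every later array. The step that reduced the deposited table to its rows is not given in the sources used here. RMA compresses changes near the background and near saturation, so a fold change of a very dim or very bright gene is understated. No detection call was used, so a low value is a level close to background rather than proof of absence. The number of arrays limits the precision.

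The deposited table held 16755 transcript clusters. The platform's annotation gave 1 gene symbol for 14996 of them, several for 1019 and none for 740. Among the clusters with 1 symbol, 14941 were found by Entrez number in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names and for the span of genes, and no coordinates are given, since its build differs from that of the probe mapping. For the 135 genes with more than 1 cluster, the cluster with the highest mean over all arrays was taken. The analysis covered 14860 genes. Of the genes fixed for display, Nr2e3, Xist and Ddx3y were not analysed here.

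Arrays were grouped by the age in the labels, with 3 arrays at P2, 5 at P28 and 4 at each of P4, P6, P10, P12 and P21. The labels do not say whether arrays of one age came from separate animals or litters, so p-values measure the spread between these samples, part of which may be technical. No 2 arrays held identical values. An array correlated with the mean of the other arrays of its age at 0.971 to 0.993. The lowest value belonged to P6 replicate 1. No scan date or other batch was used here.

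Tests used limma 3.58.1 in R 4.3.3. One linear model with a mean per age was fitted to all 28 arrays, which left 21 residual degrees of freedom, and variances were moderated with eBayes at its default settings. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, taken over all genes within a comparison, together with a change of at least 2-fold. Comparisons were the moderated F test over the 7 ages (with a span of at least 2-fold between the highest and the lowest age mean), each pair of neighbouring ages, P28 against P2, and the difference between the 4 days after P6 and the 4 days before it. Genes higher or lower at P10 than at both P2 and P28 were those called in opposite directions for P10 against P2 and for P28 against P10. Errors of log2 fold changes are moderated standard errors (SE), and errors of levels are standard deviations (SD) over arrays.

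There were 31 gene lists, fixed before the data were examined along with all comparisons, thresholds and most alternatives. They covered rod phototransduction, the outer segment and cilium, photoreceptor transcription regulators, the ribbon synapse, the retinoid cycle, cell cycle, retinal progenitors, neurite growth, oxidative phosphorylation, glycolysis, the tricarboxylic acid cycle, cholesterol synthesis, fatty acid and phospholipid synthesis, ribosome biogenesis, chromatin, splicing regulators, cell death, chaperones, immediate early genes, and the other cell types a sort could carry (cones, bipolar, horizontal, amacrine and ganglion cells, Muller glia, astrocytes, microglia, endothelium with pericytes, pigment epithelium, erythroid cells and lens). Lists were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists. The same test with an estimated correlation and limma's fry, which asks whether the genes of a list move in one direction on balance, were alternatives.

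The genes named in the text followed a fixed rule. For P28 against P2 and P10 against P6 it took the 10 largest rises and the 10 largest falls among called genes whose groups of arrays did not overlap, and for the other neighbouring ages up to 4 and 4. For the change at P6 and for P10 it took up to 5 in each direction. Symbols of uncharacterised models were left out. From each list it took up to 4 members with the largest change, and a set of rod, cone and cell cycle genes was named throughout. Genes named outside the rule are marked as chosen after their values were seen.

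The procedure was tested on simulated data with the real means and residual spread of 14860 genes, 200 of which were changed. For P28 against P2, 50.0% of the genes changed 2-fold, 94.0% of those changed 3-fold and 100% of those changed 4-fold were called. With P10 against P6 simulated, the shares were 60.0%, 96.0% and 100%. With P12 against P10 simulated, they were 44.0%, 94.0% and 100%. By adjusted p alone 92.0% of the genes changed 2-fold from P2 to P28 were called, so the fold threshold removed most of those missed.

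Alternatives were all clusters as rows, no fold threshold or one of 1.5-fold, dim genes left out, a second quantile normalization, cyclic loess, centring on steady genes, variance settings with trend and robust estimation, array weights, a fit restricted to the ages compared, the fit without the P6 or the P28 arrays, P4 in place of P6 and P21 in place of P28 (these last 4 chosen after seeing the data), the replicate number as a block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.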

Results

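Gene expression was measured in GFP-positive rods sorted from the retinas of Nrlp-GFP mice at postnatal days 2, 4, 6, 10, 12, 21 and 28, with 28 arrays in all (3 at P2, 5 at P28 and 4 at every other age). The course runs from the last rod births to the mature retina, and the series asks how the rod transcriptome, which the transcription factor NRL regulates, changes over that time. Nrl itself, whose promoter marks the sorted cells, stood at 9.67 ± 0.11 (log2, SD, n = 3) at P2 and at 9.95 ± 0.08 (SD, n = 5) at P28, a difference of 0.28 ± 0.08 (SE) that stayed below the 2-fold threshold. The first principal component of all genes carried 51.9% of the variance between arrays. Over the 7 ages, 2311 of 14860 genes (15.6%) changed by the F test with a span of at least 2-fold, and 6118 passed on adjusted p alone.

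From P2 to P28, the phototransduction genes Gnat1 and Pde6a had the largest rises, and Fabp7, Mki67 and Top2a the largest falls. Gnat1, the alpha subunit of rod transducin, rose 72.4-fold, from a log2 level of 7.04 ± 0.16 (SD, n = 3) to 13.22 ± 0.07 (SD, n = 5). Pde6a, a catalytic subunit of rod phosphodiesterase, rose 51.4-fold (log2 change 5.68 ± 0.17, SE), and the guanylate cyclase gene Gucy2f rose 41.6-fold (5.38 ± 0.23). Fabp7, a fatty acid binding protein of progenitors and glia, fell 178-fold (log2 change -7.48 ± 0.41, SE), the proliferation marker Mki67 fell 70.4-fold (-6.14 ± 0.33) and Top2a, the topoisomerase of dividing cells, fell 38.8-fold (-5.28 ± 0.42). The other largest rises were those of Pdzph1 (47.5-fold), Cds1 (28.3-fold), Slc16a6 (25.7-fold), Slc24a1 (23.4-fold), Hspa1a (21.7-fold), Glt28d2 (20.9-fold) and D16Ertd472e (18.6-fold). Cds1 makes CDP-diacylglycerol, a precursor of phosphoinositides, and Slc24a1 is the rod sodium, calcium and potassium exchanger. The other largest falls were those of Cltb (37.0-fold), Tmem47 (36.9-fold), the neurogenic transcription factor Neurod4 (28.8-fold), Txnip (26.1-fold), Slitrk6 (25.9-fold), Rtl8c (24.5-fold) and the cone channel subunit Cngb3 (24.0-fold). Adjusted p for these 20 genes was 1.15e-07 or lower, and no array of one age overlapped the other age.

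Of the 20 genes of rod phototransduction measured, 18 rose and 0 fell between P2 and P28 (camera adjusted p = 6.19e-35). Pde6b rose 3.59-fold and Sag, the rod arrestin, 3.37-fold, both from levels that were already high at P2 (10.82 ± 0.17 and 11.03 ± 0.16, SD, n = 3). In the outer segment and cilium list 6 of 22 genes rose, among them Impg1 (2.88 ± 0.16, log2 change and SE), Fam161a (2.10 ± 0.11), Prph2 (1.88 ± 0.09) and Fscn2 (1.60 ± 0.16), with a camera adjusted p of 1.32e-12. Of 23 genes of the ribbon synapse, 9 rose and 1 fell (camera adjusted p = 0.000197), led by the calcium channel subunit Cacnb2 (3.43 ± 0.11), Cplx4 (3.22 ± 0.11), Cabp4 (2.62 ± 0.16) and Slc17a7, the vesicular glutamate transporter (2.43 ± 0.13). Rdh12 (3.92 ± 0.19) and Abca4 (3.54 ± 0.13) rose among 7 genes of the retinoid cycle (camera adjusted p = 0.00709), while Rdh11 (0.65 ± 0.31) and Rdh13 (-0.16 ± 0.11) did not pass the test. Of 18 glycolysis and lactate genes 8 rose and 2 fell (camera adjusted p = 7.32e-06), with the monocarboxylate transporter Slc16a1 (3.31 ± 0.18), Pfkfb2 (3.17 ± 0.12), hexokinase Hk2 (3.03 ± 0.22) and Nxnl1 (2.20 ± 0.14) highest. With an estimated correlation between genes, these 5 lists kept an adjusted p between 3.95e-05 and 0.0306, and no other list did.

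The list of photoreceptor transcription regulators moved both ways, with 3 genes up and 4 down of 15 and no call for the list (camera adjusted p = 0.280). Mef2c (3.70 ± 0.20) and Esrrb (3.39 ± 0.11) rose, and Prdm1, which restrains bipolar fate in rod precursors, fell (-3.09 ± 0.12) with Six6 (-2.52 ± 0.21). Otx2, which specifies photoreceptors, fell 3.10-fold, from 12.50 ± 0.07 (SD, n = 3) to 10.86 ± 0.17 (SD, n = 5). Crx changed by -0.74 ± 0.10, below the threshold, and so did the lamin B receptor gene Lbr (-0.54 ± 0.16), whose loss is a feature of rod nuclei.

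Of 36 cell cycle genes 18 fell and 0 rose between P2 and P28, with Tpx2 (-3.44 ± 0.22) and Kif11 (-2.92 ± 0.31) after Mki67 and Top2a. Cyclin D1, Ccnd1, fell 5.89-fold. The camera adjusted p was 5.55e-12, and the adjusted p was 0.132 with an estimated correlation. Of 17 progenitor genes 5 fell, among them Pax6 (-2.52 ± 0.30), Sox2 (-2.14 ± 0.28) and Lhx2 (-1.56 ± 0.18), with a camera adjusted p of 9.53e-05 and an adjusted p of 0.135 with an estimated correlation. In the neurite growth and migration list 11 of 23 genes fell, led by Robo2 (-4.06 ± 0.23), Epha5 (-3.68 ± 0.16), Nrp1 (-2.47 ± 0.20) and Tubb2b (-2.35 ± 0.30), with a camera adjusted p of 6.49e-07 and an adjusted p of 0.135 with an estimated correlation. In oxidative phosphorylation 9 of 40 genes fell and 0 rose, with Ndufa1 (-1.67 ± 0.21), Cox4i1 (-1.41 ± 0.15), Ndufs4 (-1.34 ± 0.16) and Cox6b1 (-1.27 ± 0.16) lowest (camera adjusted p = 3.71e-06, adjusted p = 0.132 with an estimated correlation). Bright genes as a whole also fell, and the 1818 genes with a mean level above 9 had a median change of -0.34 against -0.03 in the others. After cyclic loess Ndufs4 (-0.98) and Cox6b1 (-0.88) no longer reached 2-fold, and Cox6b1 (-0.98) did not after another quantile normalization either.

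Smaller groups fell in part over the same span. Of 17 cholesterol synthesis genes 4 fell, Nsdhl (-2.78 ± 0.47), Srebf2 (-1.82 ± 0.31), Sqle (-1.11 ± 0.19) and Cyp51 (-1.10 ± 0.13), with a camera adjusted p of 0.00993 and an adjusted p of 0.177 with an estimated correlation. Of 23 chromatin genes 6 fell, led by the histone methyltransferase Ezh2 (-1.97 ± 0.09), Hmgb1 (-1.29 ± 0.15), Cbx1 (-1.20 ± 0.16) and Dnmt1 (-1.14 ± 0.11), with a camera adjusted p of 0.0344 that was 0.0527 without P28 replicate 2 and 0.271 with an estimated correlation. Nop10 (-1.26 ± 0.19) and Nop16 (-1.17 ± 0.23) fell among 24 ribosome biogenesis genes (camera adjusted p = 0.00993, adjusted p = 0.135 with an estimated correlation). Among 21 chaperones 3 fell, Calr (-1.14 ± 0.15), Pdia4 (-1.14 ± 0.14) and Canx (-1.03 ± 0.08), against a rise of Hspa1a, an inducible heat shock protein (camera adjusted p = 0.0117, downward, and an adjusted p of 0.135 with an estimated correlation). After cyclic loess the ribosome, chromatin and chaperone lists had adjusted p of 0.106, 0.247 and 0.123, and with bright genes only these and the cholesterol list had adjusted p between 0.173 and 0.213. With P21 in place of P28 the ribosome list had an adjusted p of 0.168. Sqle, Cyp51, Nop10, Nop16, Cbx1, Dnmt1, Calr, Pdia4 and Canx stayed under 2-fold both after another quantile normalization and after cyclic loess, Hmgb1 (-0.93) after cyclic loess and Nop16 (-0.98) with the replicate number as a block, while without P2 replicate 2 Sqle was at -0.89 and Cyp51 at -0.95, and without P28 replicate 2 Sqle was at -0.98. In the tricarboxylic acid cycle Got1 rose (1.32 ± 0.17) and 16 of 17 genes did not pass (camera adjusted p = 0.527, median -0.09 and mean 0.01).

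Markers of other cell types were followed as a measure of what the sort carried. Of 14 cone genes 10 fell and 1 rose, with falls of Cngb3, Gngt2 (-2.98 ± 0.23), the short-wavelength opsin Opn1sw (-2.81 ± 0.39) and Rxrg (-2.35 ± 0.20) against a rise of the cone arrestin Arr3 (1.29 ± 0.29). The camera adjusted p of that list was 0.000480 and its adjusted p was 0.140 with an estimated correlation. Of 12 amacrine genes 5 fell, among them Tfap2b (-3.30 ± 0.43), Tfap2a (-2.40 ± 0.29), Meis2 (-2.24 ± 0.12) and Gad2 (-1.81 ± 0.27), with a camera adjusted p of 0.0195 and an adjusted p of 0.278 with an estimated correlation. In Muller glia genes Dbi (-3.03 ± 0.23), Apoe (-1.87 ± 0.18), Slc1a3 (-1.70 ± 0.29) and Crym (-1.58 ± 0.27) fell, 4 of 13 (camera adjusted p = 0.0564). The endothelium and pericyte list was called upward (camera adjusted p = 0.0263, adjusted p = 0.278 with an estimated correlation), where Vtn rose (4.07 ± 0.16), Kdr fell (-2.21 ± 0.29) and the other 12 genes did not pass. This call was also lost after cyclic loess (adjusted p = 0.140), with bright genes only (0.173) and with P21 in place of P28 (0.168). Prox1 fell among 9 horizontal cell genes (-2.54 ± 0.33), Nefm among 11 ganglion cell genes (-1.61 ± 0.48), and among 13 bipolar genes Scgn (1.42 ± 0.35) and Prkca (1.38 ± 0.13) rose while Otx2 and Pcp2 (-1.06 ± 0.21) fell. The call of Nefm was lost without P2 replicate 2 (-1.47, adjusted p = 0.0515), and that of Pcp2 without P28 replicate 2 or P28 replicate 4 (-0.98 each), with the replicate number as a block (-0.97), after another quantile normalization (-0.81) and after cyclic loess (-0.83). In the astrocyte, microglia, pigment epithelium, erythroid and lens lists 0 genes changed, and these lists, like the horizontal, ganglion and bipolar cell lists, had camera adjusted p of 0.271 or higher. Median and mean differed in sign in the bipolar (0.06 and -0.05) and pigment epithelium (0.01 and -0.12) lists, and the ganglion cell list had a negative median (-0.07) and mean (-0.15) with an upward test.

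In all 1620 genes changed from P2 to P28, 368 up and 1252 down. Adjustment over each list alone left every count of risen and fallen members given for this comparison as it was. With the values quantile normalized again the split was 524 up and 814 down, and with cyclic loess it was 529 and 866. The median change of all genes was -0.041 as deposited, 0.070 with the first of these scalings and 0.022 with the second. The 1473 genes found with P21 in place of P28, an alternative chosen after seeing the data, included 301 of the risen and 933 of the fallen genes.

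**Figure D1:**
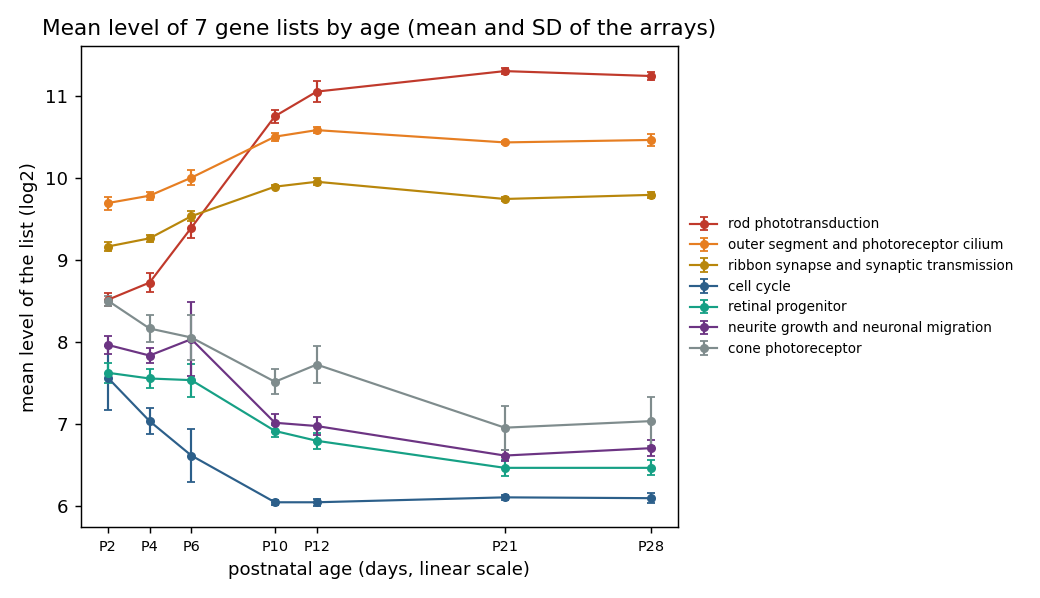
Mean log2 level of the genes of 7 lists (vertical axis) against postnatal age in days on a linear axis; points are means and bars SDs over the 3 to 5 arrays of an age. The rod phototransduction list lay at 8.51 at P2 and 11.24 at P28, and the cell cycle list at 7.56 and 6.09.

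Between P6 and P10 the rods passed through the step with the most changed genes of the course. Gnat1 rose by 3.81 ± 0.18 (log2, SE) in these 4 days, from 9.01 ± 0.28 to 12.82 ± 0.10 (log2, SD, n = 4 each), Slc24a1 rose 9.07-fold and Pde6a 7.38-fold. Mki67 fell 13.2-fold, from 8.25 ± 1.05 to 4.53 ± 0.29 (SD, n = 4 each), and stayed between 4.36 and 4.79 at every later age. Other large rises were those of Glt28d2 (3.28 ± 0.33, log2 change and SE), Pdzph1 (2.91 ± 0.21), Cdr2 (2.85 ± 0.21), Gucy2f (2.75 ± 0.23), Cds1 (2.47 ± 0.16), the guanylate cyclase activator Guca1b (2.29 ± 0.25) and the mitochondrial polymerase subunit Polg2 (2.25 ± 0.17). Large falls were those of the Myb family gene Mybl1 (-3.27 ± 0.28), Cltb (-3.09 ± 0.20), Txnip (7.99-fold), Cnn3 (-2.86 ± 0.29), Neurod4 (-2.85 ± 0.37), Rnd3 (-2.84 ± 0.28), Nfib (-2.82 ± 0.27), Ece1 (-2.81 ± 0.15) and Ccdc136 (-2.77 ± 0.15). Adjusted p for these 20 genes was 3.57e-06 or lower.

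Of the 20 phototransduction genes 8 rose from P6 to P10, and 3 of 22 outer segment and cilium genes did, Impg1 (1.34 ± 0.15), Fam161a and Fscn2 (1.13 ± 0.15). Pde6b (0.68 ± 0.09), Sag (0.85 ± 0.08) and Prph2 (0.74 ± 0.08) stayed below 2-fold. In the ribbon synapse list 6 of 23 genes rose and 1 fell, with Cabp4 (2.21 ± 0.16), Cplx4 (1.39 ± 0.10), Cacna1f (1.38 ± 0.11) and Cacnb2 highest, and Rdh12 (1.68 ± 0.19) and Abca4 (1.52 ± 0.13) rose among the 7 retinoid cycle genes. These 4 lists had camera adjusted p of 4.45e-05 or lower and 0.00136 or lower with an estimated correlation. Esrrb rose (1.94 ± 0.11) while Prdm1 (-1.29 ± 0.11) and Six6 (-1.24 ± 0.20) fell. Of 18 glycolysis genes Pfkfb2 (2.01 ± 0.12) and Slc16a1 (1.43 ± 0.18) rose, Tpi1 fell (-1.77 ± 0.28), and the list was not called (camera adjusted p = 0.334, median -0.10 and mean 0.01).

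Of 23 neurite growth genes 10 fell from P6 to P10, 11 when adjusted over the list alone, with Robo2 (-2.22 ± 0.23), Epha5 (-2.19 ± 0.15), Tubb2b (-2.19 ± 0.29) and Efnb2 (-1.81 ± 0.38) lowest (camera adjusted p = 1.34e-11, adjusted p = 0.0573 with an estimated correlation). Top2a (-2.61 ± 0.41), Ccnd1 (-1.66 ± 0.20) and Rrm1 (-1.09 ± 0.17) fell with Mki67, 4 of 36 cell cycle genes (camera adjusted p = 0.000687, adjusted p = 0.495 with an estimated correlation). Lhx2 (-1.62 ± 0.18), Pax6 (-1.48 ± 0.29), Fabp7 (-1.31 ± 0.40) and Sox2 (-1.29 ± 0.27) fell among 17 progenitor genes (camera adjusted p = 4.07e-05, adjusted p = 0.109 with an estimated correlation). Of 13 Muller glia genes 6 fell, led by Crym (-2.36 ± 0.26), Slc1a3 (-2.01 ± 0.28), Apoe (-1.76 ± 0.18) and Dbi (-1.56 ± 0.22), and this call held with an estimated correlation (adjusted p = 0.0490). Of 40 oxidative phosphorylation genes 0 passed singly while the list was called downward (camera adjusted p = 0.000843, adjusted p = 0.335 with an estimated correlation). Its call was lost with P4 in place of P6 (adjusted p = 0.366). The cell death list, where Dapk1 fell (-1.29 ± 0.17), 1 of 19 genes, was called downward (camera adjusted p = 0.00951, adjusted p = 0.109 with an estimated correlation and 0.0919 with bright genes only). The chromatin list, where Cbx5 fell (-1.13 ± 0.17), 1 of 23 genes, was called downward as well (camera adjusted p = 0.0426, adjusted p = 0.367 with an estimated correlation). That call was also lost after cyclic loess (0.0797), with bright genes only (0.108), and without P6 replicate 3 (0.0926), P6 replicate 4 (0.0619), P10 replicate 3 (0.0732) or P10 replicate 4 (0.0689). The cone list was called downward with 3 of 14 genes, Gngt2 (-1.25 ± 0.23), Cngb3 (-1.18 ± 0.16) and Opn1sw (-1.28 ± 0.38), at a camera adjusted p of 0.0369 that was 0.482 with an estimated correlation. Its call was lost without P6 replicate 1 (adjusted p = 0.106), P6 replicate 3 (0.072) or P10 replicate 2 (0.0872), and with bright genes only (0.140).

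In all 565 genes changed from P6 to P10, 131 up and 434 down. The split was 191 and 324 after another quantile normalization and 174 and 362 after cyclic loess. With P4 in place of P6, chosen after seeing the data, 644 genes changed, and 123 of the 131 risen and 252 of the 434 fallen genes were among them in the same direction. Single calls were lost without P6 replicate 1, the array with the lowest correlation to its age, for Opn1sw (-1.04), Fscn2 (0.93), Rrm1 (-0.99) and Sox2 (-0.96), without P6 replicate 3 (-1.26) or P10 replicate 4 (-1.25) for Fabp7, and without P10 replicate 2 for Opn1sw (-1.15). Rrm1 stayed under 2-fold with either other scaling.

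Before P6 the changes were fewer, and from P4 to P6 most of them were rises. Otor, which encodes otoraplin, rose 10.8-fold, from 6.76 ± 0.41 to 10.19 ± 0.48 (log2, SD, n = 4 each), and Isl1, a transcription factor of bipolar, amacrine and ganglion cells, rose 9.59-fold. Rgs5, known from pericytes, rose 6.41-fold with a wide spread at P6 (8.34 ± 1.91, SD, n = 4), and Apcdd1, a Wnt inhibitor, rose 5.14-fold. Ece1 (-1.23 ± 0.15, log2 change and SE), Uhrf1 (-1.14 ± 0.21), Adcy2 (-1.09 ± 0.10) and Ccdc136 (-1.07 ± 0.15) fell. In phototransduction Gucy2f (2.00 ± 0.23), Pde6a (1.61 ± 0.17), Gnat1 (1.12 ± 0.18) and Gngt1 (1.01 ± 0.11) rose, 4 of 20 genes, and the list held with an estimated correlation (adjusted p = 0.000390). The ribbon synapse list (3 of 23 rose) and the glycolysis list (1 of 18, Pfkp, 1.24 ± 0.15) held as well, with adjusted p of 0.00753 and 0.00106 with an estimated correlation. Of 36 cell cycle genes 3 fell, Top2a (-1.51 ± 0.41), Mki67 (-1.27 ± 0.32) and Tpx2 (-1.01 ± 0.21), and the list was called downward (camera adjusted p = 1.2e-14, adjusted p = 0.0576 with an estimated correlation). The call of Mki67 was lost without P4 replicate 1 (adjusted p = 0.0819), P4 replicate 3 (0.124), P6 replicate 2 (0.0946) or P6 replicate 4 (0.0977). That of Top2a was lost without any 1 P4 array (0.056 to 0.173) or without P6 replicate 2 (0.192) or P6 replicate 4 (0.165), after cyclic loess (0.0547) and with the replicate number as a block (0.063). Tpx2 was between -0.97 and -0.84 without P4 replicate 1, 3 or 4 or P6 replicate 2 or 4, and Gngt1 between 0.90 and 0.97 without P4 replicate 2, P6 replicate 3 or P6 replicate 4 and after another quantile normalization. The oxidative phosphorylation list was called upward with 0 of 40 genes passing singly (median 0.16, camera adjusted p = 0.000367, adjusted p = 0.167 with an estimated correlation). Several lists of other cell types were higher at P6 than at P4 too, while the cone list was lower (camera adjusted p = 0.0325, adjusted p = 0.36 with an estimated correlation). Isl1, Scgn (1.37 ± 0.34) and Vsx1 (1.28 ± 0.17) rose among 13 bipolar genes (adjusted p = 0.00913 with an estimated correlation), and Crym (1.57 ± 0.26), Rlbp1 (1.17 ± 0.19) and Slc1a3 (1.12 ± 0.28) rose among 13 Muller glia genes (camera adjusted p = 1.36e-05, adjusted p = 0.0793 with an estimated correlation). The call of Scgn was lost without any 1 P4 array or without P6 replicate 1, 3 or 4 (adjusted p from 0.0565 to 0.117), and that of Slc1a3 without P4 replicate 1, 3 or 4 or P6 replicate 1 or 3 (0.0672 to 0.128).

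In all 84 genes changed from P4 to P6, 72 up and 12 down, and 36 did so when only the 8 arrays of these ages were fitted. The call of Rgs5 was lost without P4 replicate 1 (adjusted p = 0.0568), P6 replicate 1 (0.0615) or P6 replicate 3 (0.0594), those of Gnat1 (0.82) and Uhrf1 (-0.96) without P4 replicate 2, and that of Ccdc136 (-0.96) without P6 replicate 2. From P2 to P4, 0 genes rose and 4 fell, among them the mitotic genes Tpx2 (-1.61 ± 0.23) and Bub1 (-1.28 ± 0.17) and Mgst1 (-1.06 ± 0.14), with 2610318N02Rik, chosen after its value was seen, as the remaining one, and the cell cycle list was called downward (camera adjusted p = 7.06e-22, adjusted p = 0.0576 with an estimated correlation). Of the 36 cell cycle genes 2 fell, and 5 did when adjusted over the list alone. The phototransduction (camera adjusted p = 8.57e-08) and ribbon synapse (0.000851) lists were called upward with 0 genes passing singly, each with an adjusted p = 0.0576 with an estimated correlation. The count of 4 was 12 without P2 replicate 3 and 0 when only the arrays of P2 and P4 were fitted. Mgst1 was under 2-fold without P2 replicate 1 (-0.99) or P4 replicate 2 (-0.94).

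**Figure D2:**
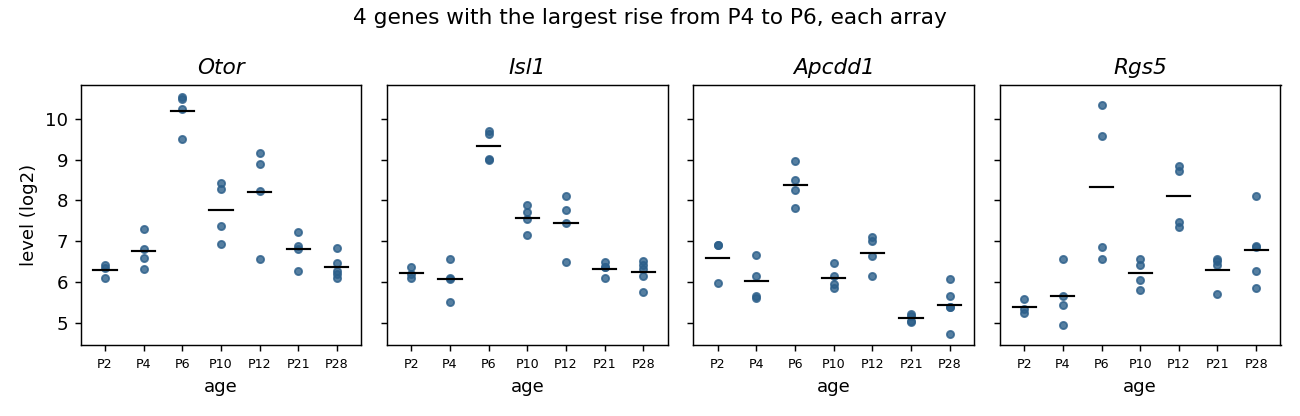
Log2 level (vertical axis) of Otor, Isl1, Apcdd1 and Rgs5 at each of the 7 ages; points are single arrays and bars are means of the 3 to 5 arrays. All 4 P6 arrays lie above every P4 and P10 array for Otor, Isl1 and Apcdd1, while Rgs5 at P6 spreads from 6.57 to 10.35.

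From P10 to P12 no gene passed both thresholds, while the 368 genes that rose from P2 to P28 made 15.1% of their summed rise. With limma 0 genes met both thresholds, 4 passed on adjusted p alone, and 803 had an unadjusted p under 0.05. The 4 were Tnfaip3 and Aqp1, higher at P12, and Arhgap31 and Celf3, lower at P12, all chosen after their values were seen. Larger differences without a call occurred. Rgs5, chosen here after its values were seen, ran from 5.81 to 6.57 at P10 and from 7.36 to 8.85 at P12. The count of genes past both thresholds was 6 without P12 replicate 3, 4 with array weights and 1 with other scalings. Gnat1 stood at 12.82 ± 0.10 and 13.16 ± 0.11 (SD, n = 4 each). The phototransduction list was called upward at a median log2 change of 0.21 (camera adjusted p = 5.97e-09, adjusted p = 0.0891 with an estimated correlation), and 1 of its 20 genes passed when adjusted over the list alone. The glycolysis list was called upward as well (camera adjusted p = 0.000914, adjusted p = 0.194 with an estimated correlation).

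From P12 to P21 most of the changed genes fell. Fabp7 fell 21.8-fold, from 10.62 ± 0.59 to 6.18 ± 1.18 (log2, SD, n = 4 each), and Tceanc2 (-3.31 ± 0.34, log2 change and SE), Psd2 (-2.44 ± 0.18) and Riiad1 (-2.43 ± 0.26) fell. Sh2d1a (2.67 ± 0.26), Hk2 (2.18 ± 0.22), the guanylate cyclase activator Guca1a (2.15 ± 0.33) and the phosphate transporter Slc17a1 (2.00 ± 0.19) rose. Guca1a and Guca1b (1.01 ± 0.25) were the 2 of 20 phototransduction genes that rose (camera adjusted p = 0.00304, upward, adjusted p = 0.298 with an estimated correlation). Guca1b was under 2-fold without P12 replicate 3 (0.75) or P21 replicate 2 (0.99). Mef2c rose (1.64 ± 0.20), 1 of 15 transcription regulators, in a list called downward (camera adjusted p = 0.00655, adjusted p = 0.10 with an estimated correlation). Nrxn3 fell (-1.18 ± 0.14), 1 of 23 ribbon synapse genes, and that list was called downward as well (camera adjusted p = 0.00304, adjusted p = 0.0777 with an estimated correlation). Of 21 chaperones, Calr (-1.08 ± 0.15) and Hspa5, the main chaperone of the endoplasmic reticulum (-1.04 ± 0.13), fell, and that list held with an estimated correlation (adjusted p = 0.0188). After another quantile normalization Calr (-0.89) and Hspa5 (-0.88) were under 2-fold, as they were after cyclic loess (-0.85 and -0.79), and so were Calr without P21 replicate 1 (-0.99) and Hspa5 without P12 replicate 3 (-0.96). Of 14 cone genes Cngb3 (-2.35 ± 0.16) and Pde6c (-1.14 ± 0.25) fell, 4 when adjusted over the list alone (camera adjusted p = 5.48e-06, adjusted p = 0.10 with an estimated correlation). The oxidative phosphorylation list was called downward with 0 of 40 genes passing singly (camera adjusted p = 1.01e-06, adjusted p = 0.10 with an estimated correlation). In all 145 genes changed, 37 up and 108 down.

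From P21 to P28 the count was 23 genes, 4 up and 19 down. Arxes1 (1.51 ± 0.30), the elongation factor gene Tcea1 (1.18 ± 0.22) and Spcs2 (1.06 ± 0.24) rose, with Mospd1, chosen after its value was seen. Nsdhl, an enzyme of cholesterol synthesis (-1.96 ± 0.43), Dcun1d4 (-1.68 ± 0.34), Ubl5 (-1.47 ± 0.30) and the ribosomal protein gene Rps18 (-1.44 ± 0.29) fell. The oxidative phosphorylation list was again called downward with 0 of 40 genes passing singly (camera adjusted p = 1.15e-05, adjusted p = 0.292 with an estimated correlation). The count was 1 when only the 9 arrays of these ages were fitted and 38 without P28 replicate 1, and Spcs2 lost its call without P21 replicate 1 (adjusted p = 0.0656), P28 replicate 4 (0.98) or P28 replicate 5 (0.98), and with the replicate number as a block (0.98, adjusted p = 0.0509).

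Set against the whole course, the step from P6 to P10 held 45.0% of the summed rise of the 368 risen genes and 49.4% of the summed fall of the 1252 fallen genes. It was the largest step for 64.4% of the risen and 61.9% of the fallen genes. Per day, the rise was 11.25% in this step, 10.05% from P4 to P6 and 7.55% from P10 to P12. Per day, the fall was 12.35% in this step, 7.45% from P2 to P4, 1.5% from P4 to P6 and 2.61% over the 9 days from P12 to P21, which held 23.5% of it. A raised level at P6 would enlarge the fall from P6 to P10 and shrink the fall from P4 to P6. Of the 434 genes called fallen from P6 to P10, 252 were also called fallen from P4 to P10.

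**Figure D3:**
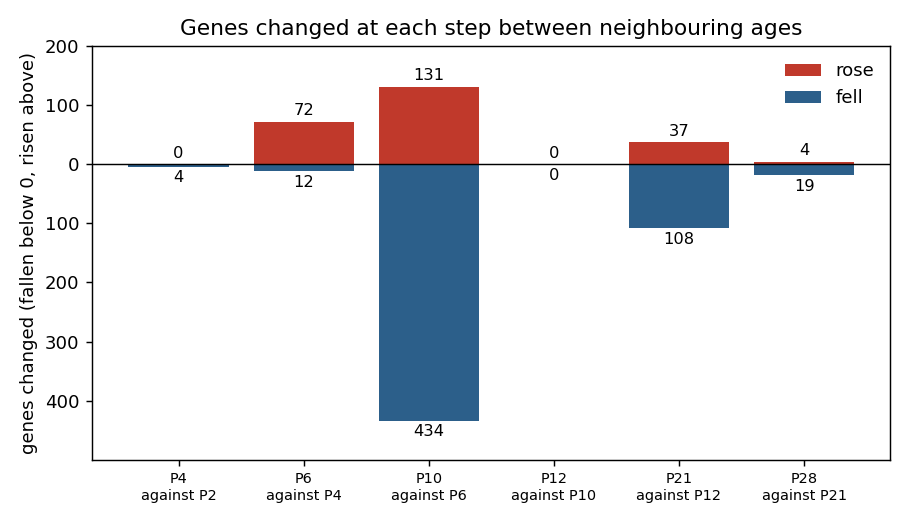
Number of genes changed (vertical axis, fallen genes drawn below 0) for each pair of neighbouring ages (horizontal axis). The step from P6 to P10 has 131 risen and 434 fallen genes and the step from P10 to P12 has 0.

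The steps of 4 days before and after P6 were compared directly, gene by gene. Gpsm2 had the largest positive difference between the later and the earlier step, 2.90 ± 0.39 (log2, SE), with means of 7.09 at P2, 6.18 at P6 and 8.18 at P10, followed by Pdzph1 (2.76 ± 0.37), Cdr2 (2.69 ± 0.37), Stk17b (2.49 ± 0.47) and Glt28d2 (2.46 ± 0.58). Otor had the most negative difference (-6.33 ± 0.71), followed by Rgs5 (-5.07 ± 1.07), Isl1 (-4.86 ± 0.46), the metallothionein gene Mt2 (-4.29 ± 0.96) and Car10 (-4.24 ± 0.53). Otor, Isl1 and Car10 rose before P6 and were lower again at P10. Of the 387 genes with a difference past the threshold, 70 were positive and 317 negative. Of the positive ones 28 had a higher mean after each step and 42, Gpsm2 and Stk17b among them, a lower mean at P6 than at P2. Of the negative ones 268 had a higher mean at P6 than at P2. The count was 225 (72 positive, 153 negative) without P6 replicate 1 and 205 with only the 11 arrays of these ages. The split was 111 and 232 after another quantile normalization, 92 and 233 after cyclic loess.

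Few genes were higher, or lower, at P10 than at both P2 and P28. Psd2, a guanine nucleotide exchange factor, rose by 2.64 ± 0.20 (log2, SE) from P2 to P10 and fell by 2.90 ± 0.17 from there to P28, and Pcp4, a calmodulin regulator, rose by 2.72 ± 0.42 and fell by 2.16 ± 0.37. Duxbl1, Olfr1372-ps1 and Dynlrb2 followed, with log2 changes after P10 of -2.61, -1.78 and -2.29. Prim1, a primase subunit, fell by 2.00 ± 0.33 and rose again by 1.65 ± 0.29, and Cdkn2c, Pole4 and the chromatin remodeller Hells were also lower at P10 than at P2 and P28, as was C130071C03Rik, chosen after its values were seen. In all 19 genes were higher and 5 lower at P10 than at both P2 and P28. Other ages did not enter this test, and Otor, Isl1 and Car10, among the 19, had higher means at P6 than at P10. Both comparisons share the P10 arrays, and 20 simulations of unchanged groups gave 0 such genes. Independent lists of these sizes would share 3.4 genes in the first direction and 3.5 in the second. With replicates 1 and 2 of P10 set against P2 and replicates 3 and 4 against P28 the counts were 18 and 4, and 14 and 4 with the replicates exchanged.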

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

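The tests in this part were chosen after the results were seen, except the test of matched random lists for oxidative phosphorylation.

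In all 34 genes rose from P4 to P6 and fell from P6 to P10, among them Otor, Isl1, Apcdd1, Rgs5 and Prox1, against 2.1 expected from independent lists. The 2 comparisons share the P6 arrays, but 26 and 20 genes were found with separate P6 arrays for the rise and the fall. Without P6 replicate 1, 20 of the 34 kept both calls, which argues against that array as the whole cause, while Rgs5, at 9.57 and 10.35 in replicates 1 and 3 and 6.85 and 6.57 in the others, did not. With cones left out, 6 of 11 lists of other cell types were higher at P6 than at P4 by the preset correlation (1 with an estimated correlation) and 0 lower, while the cone list was lower (camera adjusted p = 0.0325), so cells of some other types in the P6 sorts, which the sort for GFP would be meant to remove, may contribute. A state of rods at P6 remains open and was not tested.

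The fall of oxidative phosphorylation genes from P2 to P28 (median -0.70) was set against 10000 random lists matched on mean level and gene span. It lay at percentile 3.63 of them (middle 95% of random medians -0.73 to -0.16), and at percentile 0.04 with a match on level alone, so a trend of bright genes with a short span may account for much of it. Medians of other groups were -0.74 for ribosomal proteins, -0.68 for the proteasome and -0.39 for mitochondrial ribosomal proteins. Scaling as the whole cause is argued against, since the median nearest to 0 under other scalings was -0.39 after cyclic loess. A loss of oxidative phosphorylation transcripts in rods with age remains open and was not tested.

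If levels per cone stayed the same, a falling share of cones in the sorts would lower all cone genes above background alike. From P2 to P28, 7 of 14 cone genes differed from the list's median (-1.70) by over 1 log2 unit and over 2 SE, with Cngb3 at -4.58 and Arr3 at 1.29. Levels per cone may themselves change with age, so this spread cannot tell how much of the fall came from a falling share. Within ages, 7 of the 14 genes correlated with the mean of the other 13 over the 28 arrays, so cones in varying amounts may underlie their spread within ages. These 7 genes did not all fall from P2 to P28, since Arr3 and Opn1mw, at 1.29 and 0.89, were among them with Gnat2 (-2.12). Pearson's r was 0.60 for Arr3 (permutation p = 0.0053, adjusted p = 0.012; Spearman's rho 0.58, adjusted p = 0.011; r 0.51 without the 2 farthest arrays), 0.55 for Opn1mw (permutation p = 0.012, adjusted p = 0.023; rho 0.38, adjusted p = 0.14; r 0.38) and 0.87 for Gnat2 (permutation p = 1e-04, the smallest possible, adjusted p = 7e-04; rho 0.88, adjusted p = 7e-04; r 0.87). Cngb3 (r 0.05, permutation p = 0.82, adjusted p = 0.82; rho 0.14, permutation p = 0.56, adjusted p = 0.6; r 0.36 without the 2 farthest arrays) did not vary with them. A fall of cone genes within rods remains open and was not tested.

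Single arrays lay far from the others of their age in 12 of 282 sets of values, where chance gives about 1 in 20. The number after each is the gap to the nearest array as a share of the range. In P12 replicate 3 the rod phototransduction mean was 10.85 against 11.09 to 11.13 (0.834). In P10 replicate 2 the retinoid cycle mean was 8.79 against 8.90 to 8.91 (0.916). In P6 replicate 1 the glycolysis mean was 8.96 against 8.70 to 8.74 (0.847). In P28 replicate 2 the tricarboxylic acid cycle mean was 8.83 against 9.05 to 9.08 (0.870). In P12 replicate 2 the ribosome biogenesis mean was 8.29 against 8.23 to 8.24 (0.932). The chaperone mean was 8.98 in P10 replicate 1 against 8.82 to 8.84 (0.883), and 8.49 in P28 replicate 1 against 8.67 to 8.71 (0.801). In P4 replicate 3 the erythroid mean was 6.55 against 6.42 to 6.44 (0.862). Gnat1 was at 7.02 in P4 replicate 2 against 8.12 to 8.25 (0.890). P21 replicate 1 was lowest for Prph2 (12.17 against 12.23 to 12.24, 0.959), Opn1sw (7.31 against 8.06 to 8.16, 0.888) and Arr3 (6.29 against 7.12 to 7.16, 0.964).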

How the results depend on the processing

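The fits without the P6 or P28 arrays and those with P4 in place of P6 or P21 in place of P28 were chosen after the results were seen. No call of a named gene or of a single list reversed under any alternative run. The median change of all genes from P2 to P28 did change sign, from -0.041 as deposited to 0.07 after another quantile normalization and 0.022 after cyclic loess. Over 310 values of named genes, 1192 of 1240 alternatives kept direction and side of the threshold and 48 fell short of it. With an array left out 2403 of 2485 did, 80 fell short and 2 passed anew. For single lists 134 of 168 alternatives kept the call, and 216 of 224 with an array left out. Arrays limit small changes of dim genes, since signal close to background is compressed. Where a count moved, the cause was not tested, except that looser thresholds can only add genes. Fits with fewer arrays moved counts in both directions.

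Without a fold threshold the counts were 6118 over the 7 ages, 12 (P4 against P2), 351 (P6 against P4), 2804 (P10 against P6), 4 (P12 against P10), 1014 (P21 against P12), 368 (P28 against P21), 4844 (P28 against P2), 616 for the change at P6 and 236 for P10 against both P2 and P28. With a 1.5-fold threshold they were 4639, 12, 229, 1544, 4, 487, 153, 3220, 584 and 94 in that order. With only the ages compared in the fit they were 0 (P4 against P2), 36 (P6 against P4), 1 (P28 against P21) and 205 (change at P6). With bright genes only, P4 against P2 and P12 against P10 gave 1 each. P12 against P10 also gave 1 after another quantile normalization, after cyclic loess and when centred on steady genes. Array weights gave 8 (P4 against P2) and 4 (P12 against P10). With an estimated correlation 5 lists were called for P28 against P2, 5 for P10 against P6 and 5 for the other neighbouring ages, and fry called 24 for P10 against P6.

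With each array left out in turn, counts ran from 3 to 12 for P4 against P2 (12 without P2 replicate 3), from 0 to 6 for P12 against P10 (6 without P12 replicate 3), from 18 to 38 for P28 against P21 (38 without P28 replicate 1) and from 225 to 578 for the change at P6 (225 without P6 replicate 1). They ran from 2262 to 2428 over the 7 ages, 75 to 109 for P6 against P4, 442 to 668 for P10 against P6, 123 to 147 for P21 against P12 and 1565 to 1734 for P28 against P2. Without the P6 arrays 2137 genes changed over the ages and without the P28 arrays 1912. Deviations of arrays from their age means were correlated between ages, and in 0 of 21 pairs of ages was every same-number correlation over 0.1. Same-number correlations ran from -0.109 to 0.287. Their mean was 0.036, against -0.011 for other numbers, so a weak effect shared by replicate number is not excluded. With the number as a block 1620 genes changed from P2 to P28 and 566 from P6 to P10. Top2a (P6 against P4, -1.51), Tfap2b (P21 against P12, -1.39), Spcs2 (P28 against P21, 0.98), Nop16 (P28 against P2, -0.98) and Pcp2 (P28 against P2, -0.97) then lost their calls.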

Other observations

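The comparison of real and other groupings was planned, and no test in this part was chosen after the results were seen.

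Genes of lipid synthesis, cell death, splicing and the immediate early response moved in part between P2 (n = 3) and P28 (n = 5). Of 20 fatty acid and phospholipid genes 3 rose and 5 fell, with Cds1 (log2 change 4.82 ± 0.16, SE) against the elongase Elovl2 (-2.15 ± 0.17) and the desaturases Fads1 (-2.03 ± 0.14) and Fads2 (-1.98 ± 0.21). That list was not called (camera adjusted p = 0.527), and its median (-0.10) and mean (-0.09) were negative with an upward test. Among 19 cell death genes the survival factor Bcl2l1 (-1.95 ± 0.15), Dapk1 (-1.68 ± 0.18) and Parp1 (-1.24 ± 0.12) fell and the caspase inhibitor Xiap rose, with a camera adjusted p of 0.256 for this span. Parp1 was under 2-fold after another quantile normalization (-0.92) and after cyclic loess (-0.94).

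Of 22 splicing regulators Mbnl1 rose (1.91 ± 0.09, log2 change and SE) and Msi1 fell (-1.53 ± 0.13), with a camera adjusted p of 0.527. Of 19 immediate early genes, which respond to handling of tissue, Btg2 (-2.23 ± 0.29), Jun (-1.41 ± 0.17) and Dusp1 (-1.09 ± 0.14) fell, with a camera adjusted p of 0.138. Dusp1 was at -0.99 without P28 replicate 3, at -0.84 after another quantile normalization and at -0.90 after cyclic loess.

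Other groupings of the same arrays into groups of the same sizes were counted with the real one included. Chance was excluded for P6 against P4 (84 genes, highest other 9, 1 of 35 groupings as large), P10 against P6 (565, highest other 1, 1 of 35) and P21 against P12 (145, highest other 0, 1 of 35). It was also excluded for P28 against P2 (1620, highest other 643, 1 of 56), the 7 ages (2311, highest other 1429, 1 of 100) and P10 against both P2 and P28 (24, highest other 1, 1 of 100). For P28 against P21 the share was under that mark too (23, highest other 26, 2 of 100). Another grouping gave more genes than the real one, though, so chance was not excluded. For lists, groupings as large as the real one were few for P28 against P2 (16, highest other 16, 2 of 56) and the other neighbouring ages (44, highest other 41, 1 of 100). Groupings with no list called were 13 of 56 and 0 of 100. Lists were thus often called without the real grouping. Other groupings mix arrays of the ages compared, for lists as for genes, so differences between ages can enter them. The counts of lists alone therefore cannot decide on chance. The share was above the mark for P4 against P2 (4, highest other 4, 3 of 35) and the lists of P10 against P6 (12, highest other 14, 4 of 35). For the change at P6 (387, highest other 1332, 6 of 100) the regrouping cannot decide on chance. It exchanges arrays of P2, P6 and P10, so differences between these ages enter the contrast in other groupings. In the simulated data 4 of 14660 unchanged genes were called for the change at P6. That simulation gave each gene 1 spread for all ages and no shared shift of an array. The real spread could differ between ages, as for Mki67 (SD 1.05 at P6 and 0.29 at P10), so the simulation does not decide on chance either. For P12 against P10 the real count was 0, so all 35 of 35 groupings were as large by construction (highest other 0), which says nothing about chance.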
